A study of Mus musculus with 6 samples.

How the data were processed

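RNA was sequenced from CAD cells, a mouse line that the labels describe as catecholaminergic and of central nervous system origin, and that is also known as Cath.a-differentiated. Per the labels, 3 libraries came from undifferentiated cells kept in DMEM/F12 with fetal bovine serum, and 3 came from cells held for 5 days in the same base medium without serum, supplied with insulin, transferrin and selenium. Per the labels' protocols, RNA was column-purified with a DNase step, made into stranded libraries with a Kapa kit, and sequenced on an Illumina instrument as single-end reads of 50 bp. The labels do not say whether the libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

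Per the submitters' processing notes, the tools were FastQC 0.11.5, Trimmomatic 0.36, STAR 2.5.1a and DESeq2, with the GRCm38.p6 genome build. The read counter, its strand setting, its treatment of reads that fit several places, and the annotation release are not given in the sources used here. The values analysed here are the authors' own comparison of both groups, with 1 value per gene, and values of single libraries were not analysed here. Per the file headers, the signal of a gene is its mean normalized count. The header names no libraries, and the mean was taken here as that over the 6 libraries. The log2 fold change of differentiated over undifferentiated cells and its log2 standard error are the authors' values, with the direction taken from the name of the authors' comparison. The authors' score for each gene is a Wald statistic, which equals the fold change divided by its standard error in every row (largest difference 1.24e-13). The authors' p-value is the 2-sided normal p-value of that score, and their adjusted p-value equals a Benjamini-Hochberg adjustment over the genes that have one (largest difference 1.44e-15). The authors' deposited table holds 26436 genes, and 20285 of them have an adjusted p-value; the other 6151 have a mean normalized count of at most 2.25. A deposited sheet of KEGG pathway statistics gives a mean set statistic, a q-value and a set size for each listed pathway. Its 3 blocks of further set statistics carry headings whose numbers coincide with the sample numbers of the differentiated libraries but whose names are in no label, so they may belong to those libraries, and they were not used.

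The depth of each library was not analysed here. The mean normalized counts of all genes sum to 38846803. The median standard error of the log2 fold change was 0.13 for the 13197 genes with a mean of at least 100 and 0.65 for the rest, so that a 95% interval reached 1.19-fold and 2.43-fold to either side of the estimate.

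The plan fixed before the data were examined foresaw a count model, and its branch for a table that holds only the authors' comparison was followed. Genes were counted as changed at the authors' adjusted p under 0.05, with no test refitted. The 95% intervals are the fold change ± the normal quantile times the authors' standard error. Group means named below as implied were computed from the mean normalized count and the fold change. They take both groups as equally large and the mean as covering these 6 libraries alone, which the sources used here do not state. Of the gene IDs, 26276 matched GENCODE M21 (GRCm38), which gave the symbols, biotypes, coordinates, transcript lengths and GC contents, and 160 did not.

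There were 37 gene lists, fixed before the data were examined, of which 4 hold markers of other cell types. Each was tested against all other genes with cameraPR of limma 3.58.1 (R 4.3.3) on the authors' Wald statistic, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. The median of each list was also placed among 10000 random lists of the same size matched on mean expression. An estimated correlation, fry, splits of the libraries and fits without single libraries need library values and were not run. Called members are counted over all genes tested, and also with p-values adjusted over the list alone, which is stated where it differs.

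The named genes follow a rule fixed before the data were examined. It takes the 12 highest and 12 lowest log2 fold changes among called genes with a mean of at least 100, leaving out unnamed models and pseudogenes, up to 4 called members of each list with the largest change and the same minimum mean, a fixed set of neuronal, catecholamine and cell cycle genes, and the 4 most highly expressed genes in each group. Slc6a2 and Slc6a3, which belong to the fixed set, have no value here, and some genes that the rule takes are not reported here.

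Fold changes were simulated with the authors' standard errors over 20285 genes, of which 20085 were left unchanged. The changed genes were all drawn from those with a mean of at least 100. The count of changed genes recovered 35 of 50 genes changed 1.5-fold, 48 of 50 changed 2-fold and all 50 changed 4-fold. Of the calls, 4.69% were unchanged genes. Fold changes were drawn and tested with the same standard errors, so that share could not check whether those errors are right. Recovery at lower means, where standard errors are larger, was not simulated. Nor was a share of changed genes as large as in the data. For the gene list tests, 5.0% of 740 tests of unshifted lists had an unadjusted p under 0.05. Genes were drawn independently of each other in these simulations, so that share says nothing of lists whose members move together. The synaptic vesicle list, shifted by 0.5, 0.8 and 1.0 SD of the statistic, was called in 6, 14 and 18 of 20 draws. Smaller list shifts can thus be missed. Alternatives set before the data were examined, as far as this table allows them, were a stricter adjusted p (0.01), an adjustment over all genes with a p-value, minimum means of 10 and 100, and Fisher's exact test for the lists. Alternatives chosen after the data were seen were protein-coding genes only, 1 gene per group of identical values, other centrings, trends in transcript length, GC content and mean expression removed, a preset correlation of 0.05, and ranks of the statistic. Other tools were Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.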

Results

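Transcript levels were measured by RNA sequencing in CAD cells, a mouse catecholaminergic neuronal line that divides in serum and extends processes after serum is withdrawn. The 6 libraries comprised 3 from undifferentiated cells and 3 from cells differentiated for 5 days in serum-free medium with insulin, transferrin and selenium. A single comparison was made, of differentiated with undifferentiated cells, and it asks how the transcriptome changes with differentiation. Serum loss and the added insulin, transferrin and selenium go together with differentiation in this design, so their effects cannot be told apart. All gene values are fold changes of differentiated over undifferentiated cells, from the authors' deposited table, whose mean normalized counts sum to 38846803. The depth of single libraries was not analysed here.

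Differentiation was accompanied by lower transcripts of DNA replication, mitosis and ribosome assembly, and by higher transcripts of synaptic vesicle, ion channel, lysosomal, glycolytic and sterol synthesis genes. Of 20285 genes tested in the authors' deposited table, 7278 (35.9%) changed at an adjusted p under 0.05 by the authors' Wald test, 3689 of them higher and 3589 lower. Changes of at least 2-fold were mostly increases, with 1293 genes higher and 405 lower. That count was sensitive to expression level. Among genes with a mean normalized count of at least 100, 638 were at least 2-fold higher and 277 at least 2-fold lower. Of the called genes, 5909 were protein coding and 1075 were annotated as pseudogenes, whose reads can belong to their parent genes. Identical values were shared by 177 tested genes in 77 groups, and such copies were not measured separately.

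The genes named here and the examples given for each list are, where not otherwise said, called genes with a mean normalized count of at least 100, so genes of lower mean can have larger fold changes. In the authors' deposited table, Fmod, which encodes the matrix proteoglycan fibromodulin, rose by a log2 fold change of 7.52 (SE 0.45, Wald adjusted p 9.51e-59). The implied mean of Fmod in undifferentiated cells was only 4.29 normalized counts. Thy1, a surface glycoprotein of mature neurons, had a log2 fold change of 6.29 (SE 0.54) in the authors' deposited table. Its implied mean in undifferentiated cells was 2.77 normalized counts, so the size of that fold is poorly determined. The matrix gene Cilp (5.93, SE 0.45), the angiotensin receptor gene Agtr2 (5.12, SE 0.45) and the lipolysis inhibitor gene G0s2 (5.06, SE 0.45) followed in the authors' deposited table. Implied means of Cilp, Agtr2 and G0s2 in undifferentiated cells were also low, at 4.91, 6.04 and 6.25 normalized counts. The others of the 12 highest in the authors' deposited table were Kcnt1 (4.65), Zfp385c (4.40), Prrt4 (4.40), Fer1l6 (4.19), Thrsp (4.11), Cd74 (3.68) and Trpm5 (3.63). Kcnt1 encodes a sodium-activated potassium channel, and Trpm5 a calcium-activated cation channel. Thrsp, Cd74 and Zfp385c had the widest intervals of these, with standard errors of 0.99, 0.82 and 0.77 in the authors' deposited table.

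The lowest fold changes included inhibitors of basic helix-loop-helix factors and the enzyme that makes noradrenaline. In the authors' deposited table, Galnt5, a mucin-type glycosyltransferase gene, fell by 9.22 on the log2 scale (SE 0.76, Wald adjusted p 1.02e-31), from an implied mean of 848.1 normalized counts to 1.42, a level too low to fix the size of the fold. Id3 fell by 8.17 (SE 0.67) and Id2 fell by 5.88 (SE 0.42) in the authors' deposited table. The implied mean of Id3 in differentiated cells was only 5.74 normalized counts. Dbh, dopamine beta-hydroxylase, fell by 5.35 (SE 0.62, Wald adjusted p 3.63e-16) in the authors' deposited table, from an implied 568.6 to 13.95 normalized counts. Also among the 12 lowest log2 fold changes in the authors' deposited table were Sctr (-4.60), Adamtsl2 (-4.03), Myrip (-3.65), Fosb (-3.30), Lix1 (-3.26), Atoh8 (-3.17), Slc16a12 (-3.00) and the Wnt antagonist gene Dkk1 (-2.89). In GRCm38 coordinates, Fmod lies on chromosome 1 from 134037254 to 134048277, Id3 on chromosome 4 from 136143497 to 136145755, and Galnt5 and Dbh on chromosome 2, from 57997884 to 58045860 and from 27165233 to 27183200.

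**Figure D1:**
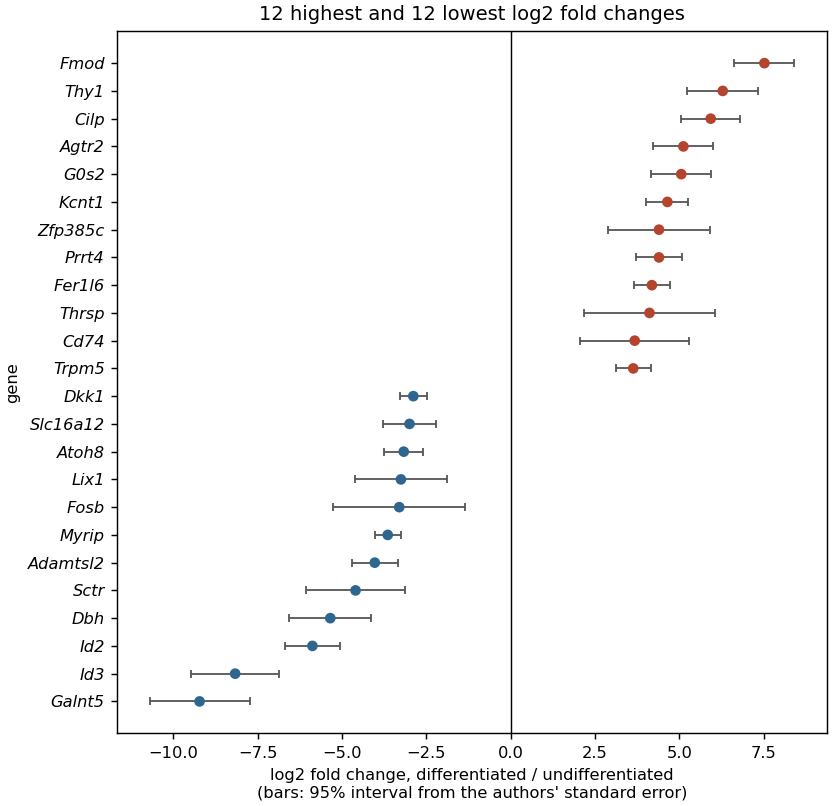
Log2 fold change (horizontal axis, differentiated over undifferentiated) of the 12 highest and 12 lowest called genes with a mean normalized count of at least 100 (vertical axis); points are the authors' estimates and bars their 95% intervals. The estimates run from -9.22 for Galnt5 to 7.52 for Fmod, and all intervals exclude 0.

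Genes of the cell cycle and DNA replication fell almost without exception. Of 36 tested members, 35 were called lower and 0 higher, with a median log2 fold change of -1.04 (cameraPR adjusted p 3.00e-35). Cdc6 (-1.85, SE 0.22), Rrm2 (-1.59, SE 0.19), Mcm5 (-1.52, SE 0.19) and Gins1 (-1.38, SE 0.13), all needed for DNA synthesis, had the largest falls in the authors' deposited table. The proliferation marker Mki67 fell by 1.09 (SE 0.14) in the authors' deposited table, which left it at an implied 9819 normalized counts in differentiated cells. Ccnd1, cyclin D1, was the member not called, at -0.17 (SE 0.11) in the authors' deposited table. Of 24 ribosome biogenesis genes, 24 were called lower (median -0.76, cameraPR adjusted p 1.49e-18), among them Utp20 (-1.19), Nolc1 (-1.17), Rrp12 (-0.97) and Heatr1 (-0.97) in the authors' deposited table.

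Cell cycle inhibitors moved less uniformly. Of 16 genes of cell cycle inhibition and quiescence, 5 were called higher and 0 lower (median 0.28, cameraPR adjusted p 0.0377), and the call was lost with a preset correlation of 0.05 (adjusted p 0.115) and with Fisher's exact test (adjusted p 0.242). Btg2 (2.03), Gas6 (1.72), the transcription factor gene Foxo3 (1.64) and Btg1 (0.99) led the increases in the authors' deposited table. The cyclin-dependent kinase inhibitor genes Cdkn1a (0.30, SE 0.19) and Cdkn1b (0.10, SE 0.11) were not called in the authors' deposited table. Of 15 p53 target genes, 5 were called higher and 2 lower, or 6 and 2 adjusted over the list alone, and the list was not called (median 0.28, cameraPR adjusted p 0.243). Eda2r (3.57), Trp53inp1 (2.92) and Btg2 rose while Aen (-0.82) fell in the authors' deposited table.

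Transcripts of growth factor response were mixed. Of 24 immediate early and growth factor response genes, 7 were called higher and 5 lower, or 7 and 6 adjusted over the list alone (median -0.07, cameraPR adjusted p 0.801). Fosb, Fos (-2.81, SE 0.85), Egr1 (-1.20, SE 0.22) and Junb (-1.13, SE 0.11) had the largest falls in the authors' deposited table. SRF and YAP target genes, which encode many actin-binding proteins, fell as a list, with 9 of 18 called lower and 1 higher, or 10 and 1 adjusted over the list alone (median -0.46, cameraPR adjusted p 0.0184). Cnn2 (-0.71), Flna (-0.54), Srf (-0.53) and Tpm4 (-0.49) were examples in the authors' deposited table, the call of Tpm4 being lost with the mean expression trend removed (adjusted p 0.0527). With a preset correlation of 0.05 the adjusted p of that list was 0.0745.

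Single genes of the catecholamine pathway changed in opposite directions, without a shift of the list. Of 13 tested genes of catecholamine synthesis and handling, 4 were called higher and 3 lower, and the list was not called (median -0.02, mean -0.24, cameraPR adjusted p 0.871, with the mean statistic on the positive side). In the authors' deposited table, Th, tyrosine hydroxylase, stood at 0.34 (SE 0.25, Wald adjusted p 0.322) with a mean of 91.3 normalized counts, and the vesicular transporter gene Slc18a2 at -0.05 (SE 0.21, Wald adjusted p 0.897). Ddc, which encodes the decarboxylase that makes dopamine, rose by a log2 fold change of 1.02 (SE 0.41, Wald adjusted p 0.0371) at a mean of 59.7 normalized counts in the authors' deposited table. That call was lost at an adjusted p under 0.01 and with the mean expression trend removed (adjusted p 0.0736). Cyb561 (1.20), Qdpr (0.79) and Slc18a1 (0.53) rose while Dbh fell in the authors' deposited table. Slc18a1 was no longer called when fold changes were centred on the median protein-coding gene (adjusted p 0.0618).

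Of 12 transcription factor genes of noradrenergic and dopaminergic neurons, 4 were called lower and 1 higher (median -0.0012, cameraPR adjusted p 0.243). The 4 lower genes were Phox2a (-0.87), Isl1 (-0.71), Gata2 (-0.69) and Nr4a1 (-0.66) in the authors' deposited table.

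Synaptic and secretory genes rose. Of 26 genes of synaptic vesicles and release, 15 were called higher and 2 lower, or 17 and 3 adjusted over the list alone (median 0.44, cameraPR adjusted p 0.000106). Rab3b (2.07, SE 0.33), Napb (1.66, SE 0.18), Syn3 (1.20, SE 0.16) and Syt4 (1.13, SE 0.18) were called members with a mean of at least 100 in the authors' deposited table, and Syn1 rose by a log2 fold change of 0.39 (SE 0.09). Snap25, a fusion protein gene, was not called at 0.41 (SE 0.18, Wald adjusted p 0.0572) in the authors' deposited table. It passed among genes with a mean of at least 10 (adjusted p 0.0489) or 100 (0.0433) and among protein-coding genes (0.0477). It also passed when centred on the implied group totals (0.0430) and with the GC content (0.0321) or mean expression trend (0.00631) removed. Under the other alternatives it was not called. Of 14 neuropeptide and dense core vesicle genes, 8 were called higher and 1 lower (median 0.39, cameraPR adjusted p 0.00158), with examples in Scg5 (1.68), Ptprn2 (1.46), Cpe (1.31) and Scg2 (0.91) in the authors' deposited table. Of 19 postsynaptic and adhesion genes, 12 were called higher and 1 lower (median 0.51, cameraPR adjusted p 0.00158), including Cntnap2 (1.29), Shank3 (0.88) and Nlgn2 (0.86) in the authors' deposited table.

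Genes of the neuronal cytoskeleton and axon growth rose in 15 of 25 cases and fell in 4 (median 0.42, cameraPR adjusted p 0.00562), and the list missed the threshold with a preset correlation of 0.05 (adjusted p 0.0514). The tubulin genes Tubb2b (1.47) and Tubb2a (1.35), the growth cone gene Gap43 (1.16), and Mapt (1.11), which encodes tau, were called higher with means of at least 100 in the authors' deposited table. Map2 (0.59, SE 0.10) and Tubb3 (0.50, SE 0.12) were also called higher, and Stmn2 (0.68, SE 0.57) was not, in the authors' deposited table. Nefl had a mean of 1.22 normalized counts and no adjusted p in the authors' deposited table. Of 30 axon guidance genes, 13 were called higher and 4 lower (median 0.48, cameraPR adjusted p 0.0299), a call lost with a preset correlation of 0.05 (adjusted p 0.124), with ranks (0.0527) and with the transcript length trend removed (0.0657). Slit3 fell by 2.67 (SE 0.15), while Efna3 (2.13), Sema6a (1.81) and Nrp2 (1.19) rose in the authors' deposited table.

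Ion channel genes rose. Of 34 voltage-gated sodium, potassium and calcium channel genes, 19 were called higher and 1 lower, or 20 and 1 adjusted over the list alone (median 0.64, cameraPR adjusted p 1.13e-06). Kcnc4 (2.73, SE 0.25), Scn3a (2.12, SE 0.17), Kcnc1 (1.50, SE 0.40) and Cacna2d2 (1.41, SE 0.48) were examples in the authors' deposited table. Neurotransmitter receptor genes went both ways, with 9 of 27 called higher and 3 lower (median 0.41, cameraPR adjusted p 0.243). The purinergic receptor gene P2rx3 (2.73), the nicotinic subunit gene Chrna5 (1.36) and the glycine receptor gene Glrb (1.07) rose, and the serotonin receptor gene Htr3a (-1.98) fell, in the authors' deposited table. Of 30 cAMP signalling genes, 11 were called higher and 2 lower (median 0.24, cameraPR adjusted p 0.00970, and 0.0745 with a preset correlation of 0.05), with examples in Rapgef3 (1.39), Prkar1b (1.38), Pde3a (1.09) and Prkar2b (0.80) in the authors' deposited table.

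Regulators of neuronal expression were not called as a list, with 7 of 20 higher and 3 lower, or 8 and 4 adjusted over the list alone (median 0.26, cameraPR adjusted p 0.165). Rbfox1 (0.99), Neurod1 (0.94), Rbfox2 (0.47) and Sox11 (0.46) rose in the authors' deposited table, the call of Sox11 being lost with the transcript length trend removed (adjusted p 0.0638). Of 26 progenitor regulators, 8 were called lower and 5 higher, or 9 and 5 adjusted over the list alone (median -0.14, cameraPR adjusted p 0.0324). Its largest falls were those of Id3, Id2 and Id1 (-2.49, SE 0.20), and Dll1 rose (1.48, SE 0.28), in the authors' deposited table. With ranks of the statistic the list had an adjusted p of 0.239, with Fisher's exact test 0.459 and with a preset correlation of 0.05 0.124. Rest, a repressor of neuronal genes, was not called (-0.16, SE 0.19) in the authors' deposited table.

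Of 17 neurotrophic factor and receptor genes, 8 were called higher and 1 lower, or 9 and 1 adjusted over the list alone (median 0.56, cameraPR adjusted p 0.0462), and the call was lost with a preset correlation of 0.05 (adjusted p 0.124), when centred on the implied group totals (0.0514) and with each trend removed. Ngfr, the low-affinity neurotrophin receptor gene, fell by 2.25 (SE 0.43), while Bdnf (1.08) and Alk (0.83) rose in the authors' deposited table, as did Gfra1, 3.99-fold. Of 20 insulin and IGF signalling genes, 9 were called higher and 2 lower (median 0.54, cameraPR adjusted p 0.000502). Igfbp5 (2.91, SE 0.23), Igf2r (2.19, SE 0.17) and Igfbp6 (2.03, SE 0.30) rose and Igfbp7 (-1.91, SE 0.25) fell in the authors' deposited table.

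Iron and selenium genes, chosen because the medium supplied transferrin and selenium, showed no shift as lists. Of 15 iron handling genes, 2 were called higher and 2 lower (median -0.03, mean 0.08, cameraPR adjusted p 0.801). Hfe (1.40) and Tfr2 (0.87) rose, Ftl1 (-0.63) fell, and the transferrin receptor gene Tfrc was not called (-0.62, SE 0.44), in the authors' deposited table. Of 24 selenoprotein and selenium handling genes, 2 were called higher and 4 lower (median 0.05, cameraPR adjusted p 0.871, with the statistic on the negative side), with Selenow (1.13) higher and Txnrd1 (-0.74), Sephs2 (-0.64) and Sephs1 (-0.49) lower in the authors' deposited table.

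Transcripts of lipid synthesis genes rose, with wide errors. Of 23 genes of cholesterol synthesis and uptake, 15 were called higher and 1 lower, or 17 and 1 adjusted over the list alone (median 0.90, cameraPR adjusted p 0.00158). Tm7sf2 (1.57, SE 0.46), Mvd (1.31, SE 0.45), Msmo1 (1.30, SE 0.49) and Dhcr7 (1.26, SE 0.49) rose in the authors' deposited table. Standard errors of this list were 2.49 times those of genes of equal mean, at the median. Mvd, Msmo1 and Dhcr7 did not pass an adjusted p of 0.01. Of 15 fatty acid synthesis genes, 7 were called higher and 0 lower (median 0.36, cameraPR adjusted p 0.0327, and 0.101 with a preset correlation of 0.05), with Scd1 (1.66, SE 0.58), Acss2 (1.65, SE 0.41), Scd2 (1.29, SE 0.45) and Fads1 (0.93, SE 0.21) as examples in the authors' deposited table.

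Of 26 glycolysis and hypoxia response genes, 21 were called higher and 0 lower (median 0.70, cameraPR adjusted p 5.14e-06). Aldoc (2.63, SE 0.99), Bnip3 (2.26, SE 0.74), Eno2 (1.68, SE 0.45) and Pdk1 (1.47, SE 0.47) had the largest changes in the authors' deposited table, and standard errors of the list were 1.91 times those of genes of equal mean, at the median. Nuclear-encoded genes of oxidative phosphorylation fell slightly, with 18 of 37 called lower and 0 higher (median -0.21, cameraPR adjusted p 0.000322), and the call was lost with the mean expression trend removed (adjusted p 0.0574). Sdhd (-0.55), Cox5a (-0.47), Atp5o (-0.47) and Cox5b (-0.37) were examples in the authors' deposited table. Mitochondrially encoded transcripts moved the other way, with 11 of 15 called higher and 0 lower (median 0.39, cameraPR adjusted p 0.00326), among them mt-Nd4 (0.53), mt-Nd6 (0.50), mt-Nd5 (0.45) and mt-Atp6 (0.43) in the authors' deposited table. The nuclear genome holds copies of these sequences, so reads can be shared.

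Lysosome and autophagy genes rose in 21 of 30 cases and fell in 0, or 22 and 0 adjusted over the list alone (median 0.43, cameraPR adjusted p 1.13e-10). Ulk1 (1.20, SE 0.18), which starts autophagy, the protease gene Ctsl (1.19, SE 0.10), and the lysosomal glucosidase gene Gaa (1.02, SE 0.09) were examples in the authors' deposited table. Of 24 amino acid response genes driven by ATF4, 15 were called higher and 0 lower, or 15 and 1 adjusted over the list alone (median 0.39, cameraPR adjusted p 1.61e-05), led by Nupr1 (2.34), Atf3 (1.61), Ddit3 (1.60) and Trib3 (1.50) in the authors' deposited table. Chaperones of the unfolded protein response were not called as a list, with 4 of 18 higher and 4 lower, or 4 and 5 adjusted over the list alone (median -0.27, cameraPR adjusted p 0.780). Herpud1 (0.61), Dnajb9 (0.57) and Sel1l (0.52) rose and Creld2 (-0.91) fell in the authors' deposited table. Of 42 cytosolic ribosomal protein genes, 15 were called lower and 0 higher, or 15 and 1 adjusted over the list alone (median -0.16, cameraPR adjusted p 0.00120), with Rps2 (-0.54), Rpl14 (-0.46), Rpl11 (-0.42) and Rpl8 (-0.39) as examples in the authors' deposited table. Their median stood at percentile 18.9 of random lists of equal expression, and the call was lost with the mean expression trend removed (adjusted p 0.295).

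Of 26 extracellular matrix and adhesion genes, 10 were called higher and 1 lower, or 11 and 1 adjusted over the list alone (median 0.86, cameraPR adjusted p 0.00164). The integrin genes Itga5 (1.93), Itga7 (1.21) and Itga6 (1.05) rose and the laminin gene Lama4 (-0.96) fell in the authors' deposited table. Of 22 interferon response genes, 12 were called higher and 0 lower, or 13 and 0 adjusted over the list alone (median 0.66, cameraPR adjusted p 0.00553), with Ifi27 (0.97), Stat2 (0.87), H2-K1 (0.86) and Tap1 (0.84) as examples in the authors' deposited table.

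Markers of other cell types were tested in small numbers. Of 5 tested markers of microglia, blood and vessels, 2 were called higher and 0 lower (median 0.91, cameraPR adjusted p 0.0304), namely Pdgfrb (2.51, SE 0.29) and Pecam1 (0.78, SE 0.18) in the authors' deposited table, and the call was lost with a preset correlation of 0.05 (adjusted p 0.0547) and with Fisher's exact test (0.335). Of 6 oligodendrocyte and Schwann cell markers, 3 were called higher and 1 lower, or 4 and 1 adjusted over the list alone (median 1.10, cameraPR adjusted p 0.580), with Cnp (0.79) higher and Pmp22 (-1.14) lower in the authors' deposited table. Of 5 astrocyte and radial glia markers, 1 was called higher (Aldoc) and 1 lower (Glul, -0.56, in the authors' deposited table), with a median of 0.11 and a cameraPR adjusted p of 0.823 on the negative side. Of 8 markers of glutamatergic, GABAergic, cholinergic and serotonergic neurons, 1 was called higher and 2 lower, including Tph2 (-0.76) in the authors' deposited table, with a median of 0.23, a mean of -0.15 and a cameraPR adjusted p of 0.683.

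**Figure D2:**
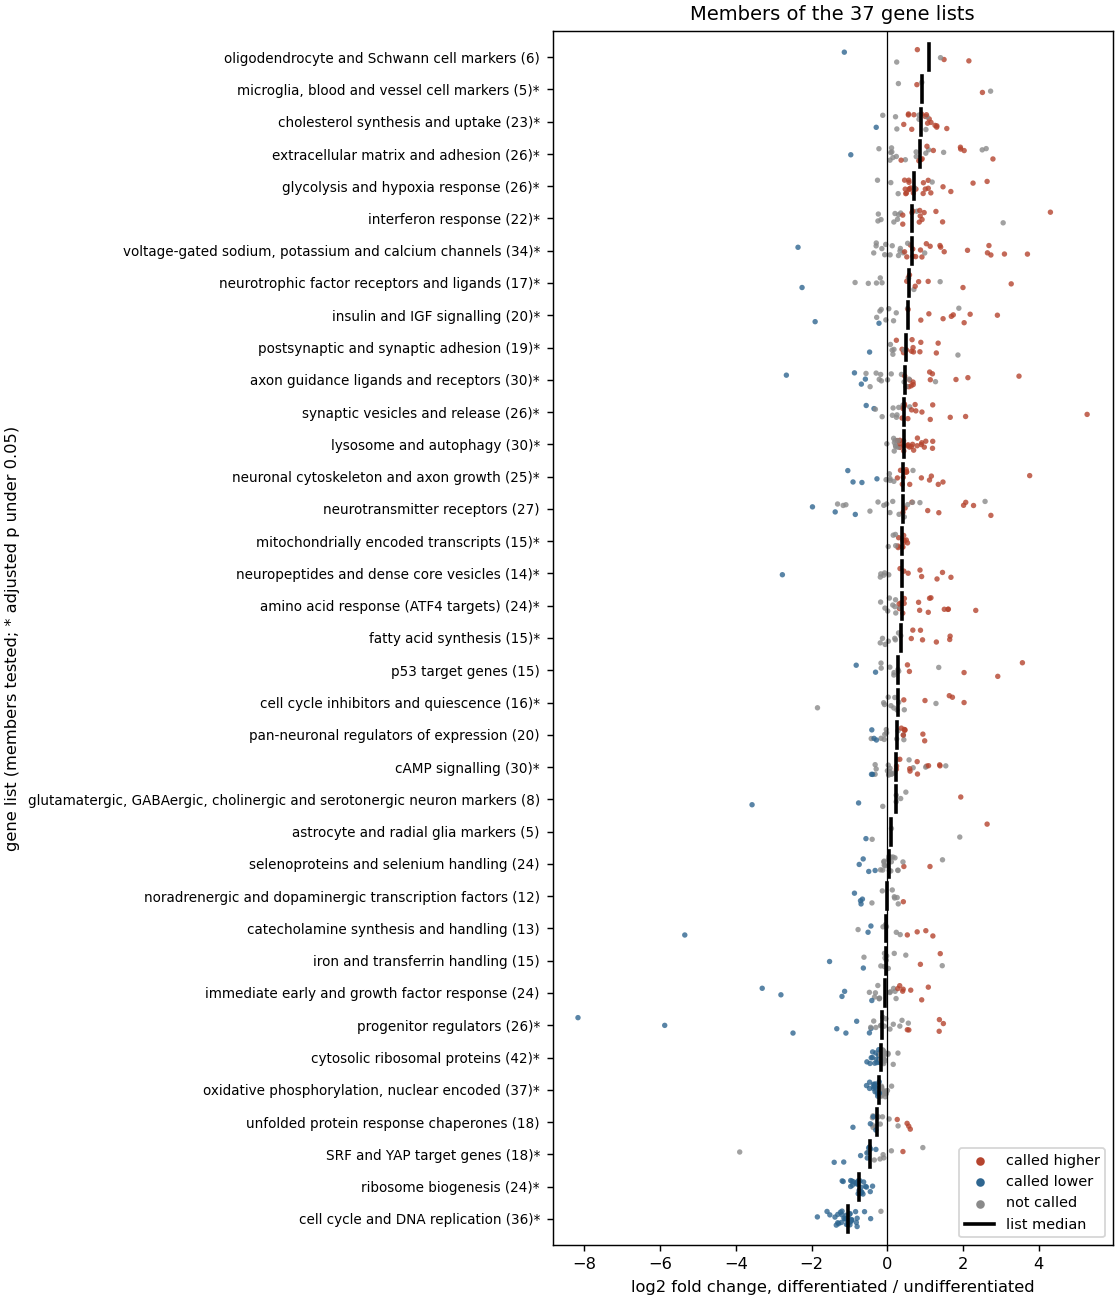
Log2 fold change (horizontal axis, differentiated over undifferentiated) of each tested member of the 37 gene lists (vertical axis), coloured by call, with a bar at each list's median and an asterisk at a cameraPR adjusted p under 0.05. List medians run from -1.04 for the cell cycle list to 1.10 for the oligodendrocyte and Schwann cell list, which was not called.

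In all, 19 lists were called higher, 6 lower and 12 not at all. Some lists not called had medians at the edge of random lists of equal expression. These were regulators of neuronal expression (percentile 99.58), oligodendrocyte and Schwann cell markers (99.51), neurotransmitter receptors (98.87), p53 targets (98.25) and unfolded protein response chaperones (2.48). The others not called lay from 35.63 to 78.85. Random members were drawn independently, so these percentiles ignore members that move together. With a preset correlation of 0.05, 16 of the 25 called lists passed, and an estimated correlation needs library values, which were not analysed here.

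Eef1a1 (0.13, SE 0.09) was among the 4 most highly expressed genes in both groups and was not called, and mt-Co1, also among them in both groups, rose by a log2 fold change of 0.41 (SE 0.14) in the authors' deposited table, a call lost with the transcript length trend removed (adjusted p 0.0512) and at an adjusted p under 0.01. Hsp90ab1 (-0.18, SE 0.10) was among the 4 most highly expressed in undifferentiated cells and was not called in the authors' deposited table. CT010467.1, annotated as ribosomal RNA and not as a protein-coding gene, was among them in differentiated cells, at 0.79 (SE 0.61, Wald adjusted p 0.338) in the authors' deposited table.

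The authors' deposited pathway sheet lists 83 KEGG pathways as higher and 28 as lower, all with q-values under 0.1, and 61 and 25 of them have q-values under 0.05. The lower pathways of smallest q were Spliceosome (mean statistic -8.43, q 7.43e-39, 128 genes), RNA transport (-7.25, q 3.04e-31), DNA replication (-7.40, q 2.07e-25), Cell cycle (-6.20, q 1.49e-23) and Ribosome biogenesis in eukaryotes (-5.97, q 1.16e-20) in the authors' deposited table. TGF-beta signaling was also listed as lower (-3.02, q 2.33e-06). The higher pathways of smallest q in the authors' deposited table were Cholinergic synapse (2.86, q 4.88e-05), PI3K-Akt signaling (2.82, q 4.88e-05), Cell adhesion molecules (2.82, q 4.88e-05), Glycolysis / Gluconeogenesis (2.78, q 6.80e-05) and Insulin secretion (2.72, q 7.40e-05). Steroid biosynthesis (2.35, q 0.00130), Lysosome (2.18, q 0.00158) and Axon guidance (2.05, q 0.00225) were listed as higher too. These statistics come from the same libraries as the gene values and are not independent of them.

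**Figure D3:**
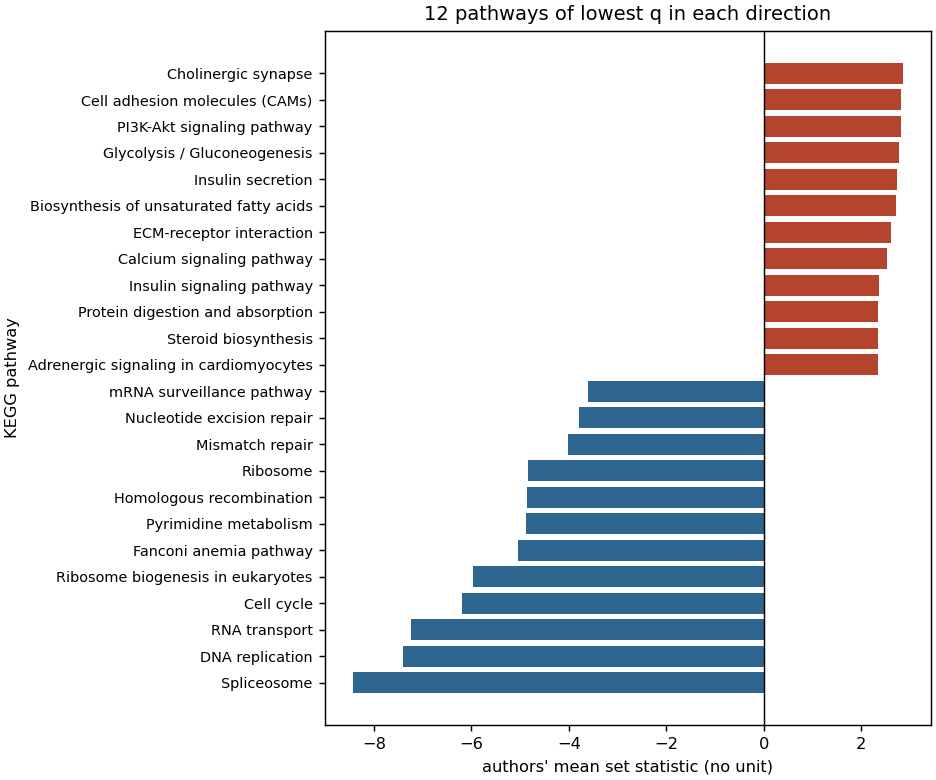
The authors' mean set statistic (horizontal axis, no unit) of the 12 KEGG pathways of lowest q in each direction (vertical axis), with positive bars for higher and negative bars for lower after differentiation. The bars run from -8.43 for Spliceosome to 2.86 for Cholinergic synapse.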

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

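Protein-coding genes only, single genes for identical values, the centrings, the removed trends, the preset correlation of 0.05, the ranks, and the list tests at a minimum mean were alternatives chosen after the data were seen, and the others were chosen before. The counts of genes changed, higher and lower stayed within 1.5 times their reported values under every alternative run, from 5451 changed genes at an adjusted p under 0.01 to 7540 when centred on the median protein-coding gene. The share of higher genes among those changed ran from 42.8% in that centring to 55.7% with the mean expression trend removed. A minimum mean of 100 lowered the count changed at least 2-fold from 1698 to 915, and its higher part from 1293 to 638, since fewer genes of low mean were then tested. A preset correlation of 0.05 lowered the called lists from 25 to 16, because a larger correlation widens the error of each list mean; under the other alternatives 20 to 25 lists were called. With protein-coding genes only, the lists of quiescence, axon guidance, neurotrophic factors, fatty acid synthesis and vessel markers were no longer called, and at a minimum mean of 100 those of SRF and YAP targets, progenitor regulators and neurotrophic factors were not. No list or named gene changed sign while called. At an adjusted p under 0.01, 13 of 176 named genes were no longer called, among them mt-Co1, Gas6, Cacna2d2, Scd1, Scd2, Trib3 and Aldoc. In addition, 3 genes not called in the report were called under 1 alternative each, namely Ccnd1 with the GC content trend removed (-0.26, adjusted p 0.0493), Eef1a1 with the mean expression trend removed (0.26, 0.0133) and Hsp90ab1 when centred on the median protein-coding gene (-0.24, 0.0350). Snap25 was called under several alternatives, as given above.

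Other normalizations, count models, count filters, pseudocounts, a replicate block, fits without single libraries, an estimated correlation, fry and the distance between libraries need values of single libraries and were not run. No paired analysis was possible because no gene values of single libraries were analysed. The labels do not say whether the sample numbers pair libraries across the groups, and whether the authors' fit took pairs into account is not given in the sources used here. Other splits of the samples were not counted for want of library values, and 3 libraries against 3 give too few splits for a share under 0.05. Depth limits the genes of low mean most, with a median standard error of 0.65 under a mean of 100 against 0.13 above it.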

Other observations

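All tests in this part were chosen after the results were seen. Among 166 families of protein-coding genes that share a symbol root (at least 8 members with a mean normalized count of at least 100), cameraPR called 23 lower and 4 higher after adjustment over the families. Lower families beyond those of the cell cycle included nuclear pore genes (Nup, 17 of 19 members called lower, median log2 fold change -0.63, adjusted p 2.49e-07), RNA polymerase subunits (Polr, 20 of 28, -0.45, 0.000456), RNA helicases (Ddx, 20 of 33, -0.30, 0.000815), splicing factors (Srsf, 8 of 10, -0.55, 0.00171) and proteasome subunits (Psmd, 11 of 14, -0.29, 0.0155). Histone genes (Hist, 10 of 18 lower and 2 higher, median -1.11, adjusted p 0.00124) are near-identical copies that can share reads. The 4 higher families included semaphorins (Sema, 7 of 8, median 0.60, adjusted p 0.00115), synaptotagmins (Syt, 7 of 8, 0.44, 0.0127) and tetraspanins (Tspan, 7 of 14, 0.44, 0.00548).

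Circadian clock genes were higher in 15 of 20 cases and lower in 1 (median 0.92), in a list drawn up after several members had been seen, so that no test is given. In the authors' deposited table Rora (2.09), Bhlhe41 (1.76), Dbp (1.64), Ciart (1.52), Cry2 (1.16) and Arntl (0.96) rose, Nr1d2 (-0.41) fell, and Clock (-0.28), Cry1 (-0.04), Per1 (0.27) and Nr1d1 (0.05) were not called. Of 9 liver X receptor target genes, 6 were called higher and 0 lower (median 0.88). This list too was drawn up after values had been seen, and Scd1 was already reported. Abca1 (3.20, SE 0.14), Pltp (1.92) and Lpcat3 (0.82) rose in the authors' deposited table. Mylip (-0.01), Apoe (mean of 49.1 normalized counts) and Nr1h3 (mean of 35.4) were not called in the authors' deposited table.

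Id1, Id2 and Id3 fell further than genes of proliferation. The upper end of the 95% interval of each lay at or below -2.09, under the 10th percentile of the cell cycle list (-1.37). The 3 genes were named for their large falls, so this order was likely from the start. Their falls were larger than those of most cell cycle genes, but the comparison does not test fewer dividing cells as a cause. With trends in GC content, transcript length or mean expression removed as medians over bins of genes, the 3 genes stayed at or below -2.42. Such trends were thus small beside these falls. Their removal could not test a bias particular to single genes. Less BMP and SMAD input once serum is gone was not decided. Of 12 BMP and SMAD response genes, 11 were called lower and 0 higher (median log2 fold change -2.31). That list was drawn up after values had been seen and holds the 3 Id genes themselves. A one-sided Fisher's exact test of 3 response genes in no earlier result gave p 0.00553, but it is void because these genes were chosen after their values had been seen. Serum loss and differentiation go together in this design, so this explanation cannot be told apart from other effects of differentiation.

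Standard errors were raised in many lists, and those of sterol genes and of glycolysis and hypoxia genes were 2.49 and 1.91 times those of genes of equal mean, at the list medians, and 7 of 23 and 5 of 26 members were not called. Counting gave at most 0.529% of the squared standard error of the median member in either list, which argues against low counts. Against genes matched on both mean and size of fold change the ratios were still 2.05 and 1.57, above all 10000 random lists, which argues against a mere effect of large folds. They are not particular to these lists, since 26 of 37 lists lay above the 95th percentile of such random lists, fatty acid synthesis (1.61) among them. A difference in culture state between libraries of a group, such as density or time since feeding, may be the source. It was not tested and is not told apart here from other sources of spread. The gene values hold 0 columns of single libraries. The 3 blocks of set statistics that may belong to the differentiated libraries were not used.

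A segment of the X chromosome (GRCm38, 24474308 to 35427093), whose ends were set after its genes had been seen, held 19 called higher and 2 called lower among 25 tested genes, and the 19 had log2 fold changes from 3.68 to 7.02 in the authors' deposited table. Their implied means were at most 3.26 normalized counts in undifferentiated and 4.56 to 58.9 in differentiated cells, and 18 of the 19 lay under 3 in undifferentiated cells, so the folds are poorly determined. The 19 genes held 14 distinct sets of values and 7 shared theirs with another, so several of these genes were not measured separately. Reads shared between near-identical copies would give such values, but how such reads were counted is not given in the sources used here. The number of distinct sets says nothing of the direction of the change. Whether transcription of these copies may have risen cannot be told apart from other sources with 0 columns of single libraries.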
